A study of Danio rerio with 7 samples.

How the data were processed

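Single-cell transcriptomes came from adult zebrafish ventricles 7 days after cryoinjury. The animals carried a reporter in which the promoter of nppa, a natriuretic peptide gene, drives mCitrine, and cells with high reporter signal were sorted 1 per well into 384-well plates. The series text names mCitrine as the sorted colour, while the treatment protocol in the labels names mCherry; this difference was not resolved here. Per the labels, 12 hearts were used per genotype. There were 3 plates from hmga1a+/+ fish (wild type) and 4 from hmga1a-/- fish (mutant). The labels give no replicate numbers. Plates were numbered here in their order of deposit within each genotype, so equal numbers pair no plates. The series text gives 768 cells isolated per genotype and 1 wild-type plate lost in sequencing, while the files hold 1152 wild-type and 1536 mutant wells; the reason for the difference is not given in the sources used here. Nothing in the labels ties a plate to separate animals, so p-values measure the spread between plates, which may be technical.

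Per the labels' protocols, libraries were made by CEL-seq2 with spike-in RNA and a UMI (a random barcode that marks each molecule). BWA 0.6.2 is named in the submitters' processing notes. The genome build and annotation are not given in the sources used here. The deposited values are estimated counts of transcripts per gene and well with 2 decimals, not whole counts. They were tested against the usual correction for UMI saturation: 100% of the 857630 values above 0 matched, to within 0.0051, a whole UMI number corrected for a space of 4096 barcodes, which is a 6-base UMI. The 4-base UMI in the labels' protocol matched 63.19% of values. The largest observed number was 2927 UMIs, and estimates of very abundant genes therefore rest on a sizeable correction. The 7 tables were joined on 16394 gene rows and 91 spike-in rows, with a gene absent from a table set to 0. The tables hold gene identifiers only. Symbols were taken from a table of names that covered 13087 of the 16394 genes; 682 symbols stood on more than 1 gene, and those genes are given with their identifier. Many symbols in that table are written in human style. No gene matched the symbol vmhc, so it is not reported. Counts of near-identical gene copies may share reads, since the counting of multi-mapped reads is not given in the sources used here.

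A cell was kept with at least 1000 transcripts that were neither spike-in nor mitochondrially encoded. Mitochondrial genes were recognised by symbol only, and 13 of the 15 listed mitochondrial symbols matched a gene. A mitochondrial gene without a symbol was therefore counted as non-mitochondrial in the filter, clustering, thinning and mitochondrial share. Of 2688 wells, 1033 were kept, 22.1% of wells in the poorest plate. No doublet caller was run because the plates were sorted 1 cell per well. Kept cells were scaled to 10000 transcripts, log-transformed and clustered together without hmga1a, mitochondrial genes and spike-ins (scanpy 1.11.5, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2). A cluster was called cardiomyocyte-like from markers fixed beforehand when its median marker share was at least 50% of that of all cells, no other cell type had more markers among its 10 leading genes, and it held at least 15 cells. A cluster led by markers of another type was clustered again first. This rule was set in 3 passes after the clusters had been seen and before any gene was tested; both earlier forms were run as alternatives. It gave 942 cardiomyocyte-like and 91 unnamed cells.

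Deposited estimates were summed per plate over cardiomyocyte-like cells, rounded to whole numbers and tested with edgeR 4.0.16 (TMM scaling, filterByExpr by genotype, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) with the sequencing run as covariate. Runs were read from the flow cell of each plate's file: run 1 held 1 wild-type and 2 mutant plates, run 2 held 2 and 2. Of 16394 genes 2171 passed the filter. Fold changes are mutant minus wild type on the log2 scale, with the standard error (SE) from the F statistic. CPM values are TMM-scaled. Differences within a run are differences of mean log2(CPM + 1). The same fit was made on sums over all kept cells. Counts were simulated from each gene's mean CPM over all plates, the plates' library sizes and the fitted dispersions. No run effect was simulated, so the setting is simpler than the data. In 5 draws with 200 changed genes each, over the 2171 genes of the cardiomyocyte-like comparison, 21.2% of genes changed 1.5-fold were called. The share called was 53.2% of genes changed 2-fold, 96.9% of those changed 4-fold and 0.3% of unchanged genes.

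Of 18 gene lists fixed before the data were examined, 14 had a tested member. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 14 lists. A minimum of 3 tested genes per list was used in a first version but was not part of the plan. It was removed after its results had been seen, by which the border zone list lost its call, and it is given as an alternative. Listed symbols were matched exactly without regard to case, which left out many zebrafish copies named with a final a or b; an extended match was an added alternative. Scores and shares per cell used cells thinned to 1000 non-mitochondrial transcripts (seed 7; no cardiomyocyte-like cell was shallower) and exact permutation tests of plate values over all 35 splits of the 7 plates, two-sided, with a smallest possible p of 0.0286.

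The genes named are hmga1a; of the genes past the threshold, with the same sign in both runs and a mean log2 CPM of at least 5, the 12 with the largest change in each direction; up to 4 members of each list with the smallest p, except 2 genes not used here; and nppa, nppb and myl7 in any case. Genes without a symbol are not named; 1 named gene with a clone-based symbol, ENSDARG00000091974, is given by its identifier. Alternatives planned beforehand were DESeq2 size factors, DESeq2 1.42.0, no low-count filter, no run covariate, each run alone, each plate left out, cell minimums of 500 and 2000, no mitochondrial genes, all kept cells, observed UMIs, equal weight of cells (limma), resolutions 0.5 and 2 for cell type shares, and other definitions of each score. Others were chosen after seeing the data and are named as such. No 2 plates held identical wells or plate sums that agreed within sampling noise: chi-square per degree of freedom between plates was at least 4.69. R 4.3.3 and Python 3.11.15 were used.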

Results

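The data cover sorted ventricular cells with high nppa reporter signal from cryoinjured hearts of hmga1a-/- and hmga1a+/+ fish. This gene codes for a chromatin-binding high mobility group protein. The comparison asks how cells of this reporter gate differ in their transcripts when hmga1a is mutated. The 3 wild-type plates held 374229, 808070 and 751800 estimated transcripts, and the 4 mutant plates held 522954, 310267, 597668 and 456362. After removal of shallow wells, 25.8%, 52.6% and 51.6% of wells remained in wild-type plates and 34.4%, 22.1%, 45.6% and 36.98% in mutant plates. The mean was 43.3% ± 15.2 in wild-type plates (SD, n = 3) and 34.8% ± 9.68 in mutant plates (SD, n = 4; exact permutation p = 0.429, two-sided), with differences of 2.47 percentage points in run 1 and -10.8 in run 2. The median kept cell held 2276 ± 548 transcripts in wild-type plates and 2270.1 ± 325.1 in mutant plates (SD, n = 3 and 4; exact permutation p = 1.0, two-sided). The difference was 824 transcripts in run 1 and -523 in run 2.

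Most kept cells were cardiomyocyte-like in both genotypes. They made up 93.98% ± 0.908 of kept cells in wild-type plates (SD, n = 3) and 87.6% ± 8.63 in mutant plates (SD, n = 4). The difference did not exceed the spread between plates (exact permutation p = 0.314, two-sided). The difference was -11.5 percentage points in run 1 and -0.658 in run 2, and the lowest share was 75.8% in mutant replicate 1. The threshold on clusters was set after they had been seen. The cells it kept out made up 6.02% ± 0.908 of wild-type (SD, n = 3) and 12.4% ± 8.63 of mutant kept cells (SD, n = 4). Within the class, cluster 2 held 28.9% of wild-type and 9.75% of mutant cells. Cluster 5 held 7.66% and 17.2%, with 57 of its cells from mutant replicate 4. All 20 cells of cluster 7.2 came from mutant plates, 14 of them from mutant replicate 1. Median mitochondrial share was 1.33% ± 0.0493 in wild-type plates (SD, n = 3) and 2.05% ± 0.872 in mutant plates (SD, n = 4; exact permutation p = 0.343, two-sided). It was 2.91% and 2.69% in the mutant plates of run 1.

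**Figure D1:**
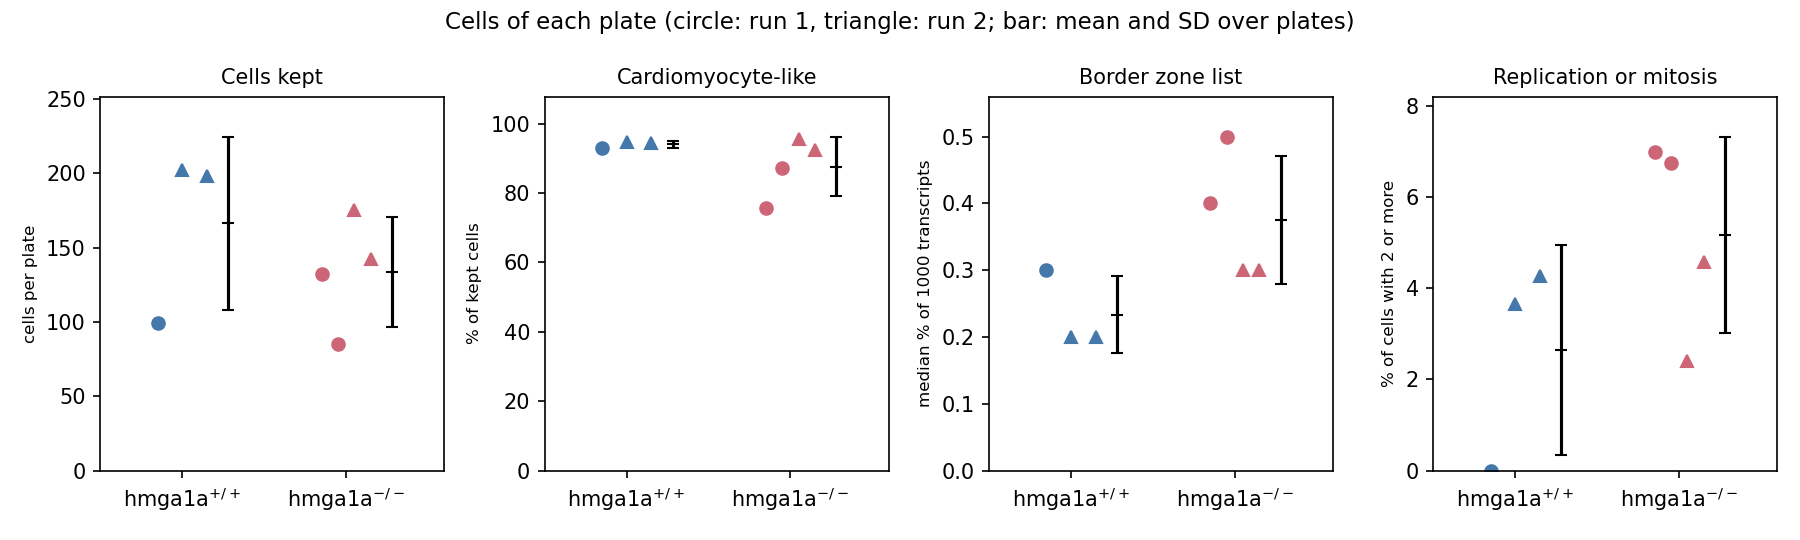
Kept cells per plate, percent of kept cells that were cardiomyocyte-like, median percent of thinned transcripts from the border zone list, and percent of cells with at least 2 replication or mitosis transcripts, by genotype. Each point is a plate (circles run 1, triangles run 2) and bars give mean and SD over 3 wild-type and 4 mutant plates; the lowest cardiomyocyte-like share, 75.8%, is in a mutant plate of run 1.

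The hmga1a transcript (ENSDARG00000028335) was lower in all 4 mutant plates than in any wild-type plate. It stood at 103.04 ± 22.4 CPM in wild-type (SD, n = 3) and 38.8 ± 21.6 CPM in mutant cardiomyocyte-like cells (SD, n = 4), a log2 fold change of -1.65 (SE 0.44). The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.0506, which did not pass the threshold over all genes. The difference was -0.80 in run 1 and -2.33 in run 2. It passed in 11 of 26 alternatives, with adjusted p from 0.00551 to 0.718. The transcript was still measured in mutant plates. The labels do not say which part of the gene is changed, so the level of the sequenced 3' tag alone does not settle whether the gene's function was lost. A transcript was found in 7.44% ± 3.62 of thinned wild-type cells (SD, n = 3) and 2.02% ± 1.65 of thinned mutant cells (SD, n = 4; exact permutation p = 0.0571, two-sided). Without thinning the shares were 14.3% and 5.68%. The thinned difference was -1.26 percentage points in run 1 and -7.48 in run 2, and the unthinned difference was 2.44 and -15.3.

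In cardiomyocyte-like cells 68 genes differed between genotypes, 38 higher and 30 lower in mutant plates (edgeR, adjusted p under 0.05). KCNV1 (ENSDARG00000070092), a modulatory potassium channel subunit, fell from 1164 ± 399.8 CPM to 35.5 ± 39.8 CPM (SD, n = 3 and 4; log2 fold change -4.89, SE 0.36, edgeR adjusted p = 7.34e-07), with 0 and 4.66 CPM in the mutant plates of run 1. The small heat shock protein gene hspb6 (ENSDARG00000077236) fell from 2442 ± 132.1 to 660.3 ± 190.8 CPM (log2 fold change -1.86, SE 0.17, edgeR adjusted p = 1.05e-05). RBP2, a retinol-binding protein gene, fell from 291.45 ± 4.66 to 39.1 ± 28.7 CPM, and FAM107B from 156.9 ± 35.5 to 20.9 ± 14.9 CPM. RBP2 was also among the 10 leading genes of cluster 2, which held a larger share of wild-type cells. The same 10 genes included ENSDARG00000091974, which was higher in mutant plates. Clusters were formed on these same transcripts, so such matches are no independent support. Lower by log2 changes between -2.48 and -1.76 were ckmb, a muscle creatine kinase gene, the phosphatase gene ptp4a2b, the cardiac transcription factor gene HAND2, the repressor gene BHLHE40, the MYC partner gene MAX, the actin gene actc1c, znf865 and si:ch211-59c24.3.

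Among the higher genes, MVP (ENSDARG00000021242), the main protein of vault particles, rose from 44.6 ± 26.3 to 381.5 ± 104.5 CPM (SD, n = 3 and 4; log2 fold change 3.08, SE 0.30, edgeR adjusted p = 1.70e-05). The interferon-induced membrane protein gene ifitm1 rose from 23.9 ± 6.98 to 171.3 ± 45.6 CPM (log2 fold change 2.75, SE 0.32). The stress-induced transcription factor gene ATF3 rose from 12.3 ± 3.43 to 121.4 ± 59.4 CPM (log2 fold change 3.30, SE 0.47). The nuclear receptor gene NR4A3 rose from 7.38 ± 6.89 to 81.1 ± 17.4 CPM and the AP-1 gene JUND from 27.5 ± 24.5 to 157.85 ± 34.97 CPM. Higher by log2 changes between 1.43 and 2.08 were ANXA2, ptmaa, the co-chaperone gene FKBP5, the tetraspanin gene CD81, MIDN, a myosin heavy chain gene listed as MYH6 (ENSDARG00000079564) and the gene ENSDARG00000091974. ANXA2 and this MYH6 gene were also among the 10 leading genes of cluster 7.1, which held 0.638% of wild-type and 4.03% of mutant cells of the class. Most of its 22 cells came from run 1: 3 from wild-type replicate 1, 11 from mutant replicate 1 and 5 from mutant replicate 2. Run 2 gave 2 and 1 cells, from mutant replicates 3 and 4. By contrast, ATF3 and FKBP5 were among the 10 leading genes of cluster 3, beside the lower genes ACADVL and si:ch211-59c24.3. Cluster 3 held 18.1% of wild-type and 12.9% of mutant cells of the class.

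All 68 genes had the same sign in run 2 alone, and so did the 65 of them tested in run 1 alone, but they were called on these same plates. Run 1 holds 1 wild-type plate, which its fit assumes to vary like the mutant plates. Run 1 alone called 89 genes, 35 of them among the 68, and run 2 alone called 45, with 29 among the 68. The count was 38 without the run covariate, 40 without wild-type replicate 1 and 44 without wild-type replicate 3. Over all kept cells, unnamed ones included, 14 genes were called, 7 in each direction, and all 14 were among the 68. There ANXA2 changed by -0.14 and MYH6 (ENSDARG00000079564) by -0.05. Single calls were lost in up to 16 of 25 alternatives (ENSDARG00000091974). They were lost in 13 of 27 for xirp1, 12 of 26 for MT-ND5, 12 of 27 for RPS21, 11 of 26 for MT-ATP6 and 10 of 26 for HAND2. The call of MYH6 (ENSDARG00000079564) was lost in 8 of 27, among them without wild-type replicate 1 and without mutant replicate 3. The count over all kept cells was 7 without wild-type replicate 1 and 9 without wild-type replicate 2 or 3.

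**Figure D2:**
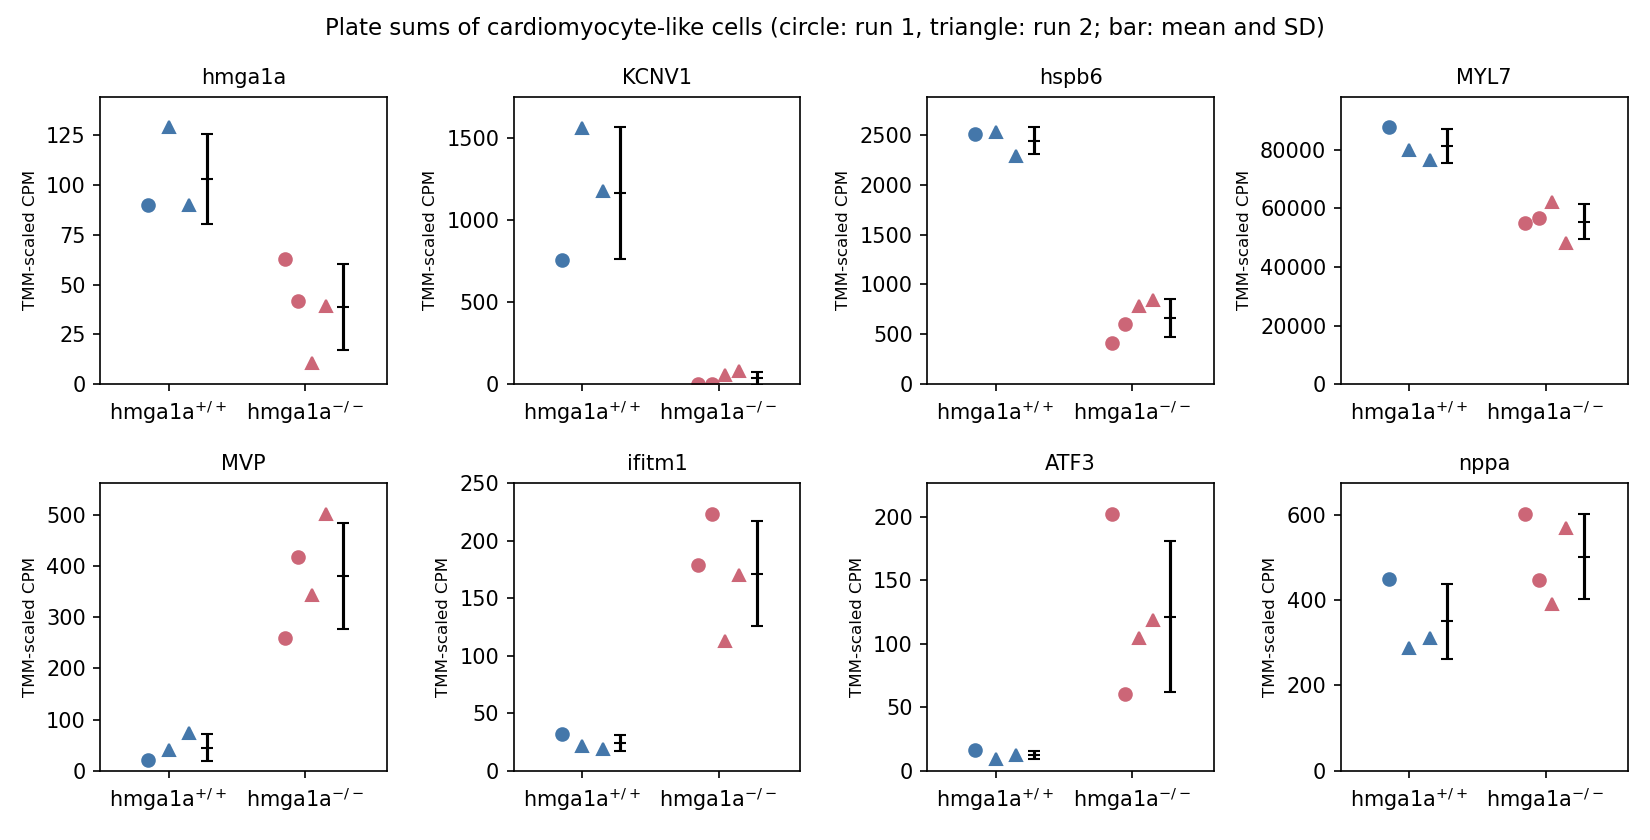
TMM-scaled CPM of 8 genes in plate sums of cardiomyocyte-like cells, by genotype, each panel on its own linear axis from 0. Points are plates (circles run 1, triangles run 2) and bars give mean and SD; KCNV1 lay at 35.5 CPM on average in mutant plates against 1164 in wild-type plates, while nppa plates overlapped.

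Genes of the contractile apparatus moved in both directions. Of 12 tested sarcomere genes 2 rose (tnnc1a and MYH6, ENSDARG00000079564) and 2 fell over all genes tested, and 2 rose and 3 fell when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.773). The cardiac myosin light chain gene MYL7 (ENSDARG00000019096) fell from 81352 ± 5738 to 55508 ± 5864 CPM (SD, n = 3 and 4; log2 fold change -0.56, SE 0.11, edgeR adjusted p = 0.0101), and the light chain gene cmlc1 changed by -0.55. The troponin C gene tnnc1a rose by 0.69 (SE 0.12). Of 7 calcium handling genes none was called by edgeR, DESeq2 or limma, nor by edgeR adjusted over the list alone, and 1 had an unadjusted edgeR p under 0.05. Their log2 fold changes included hrc 0.63, atp2a2a -0.22, CASQ2 0.16 and trdn 0.29. The list as a whole did not pass (camera adjusted p = 0.639).

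The border zone list holds genes of injured myocardium, among them both natriuretic peptide genes. The list did not pass (9 genes, median log2 fold change 0.51, camera adjusted p = 0.0527; adjusted p = 0.701 with an estimated correlation), though it passed in 10 of 30 alternatives. Its median was 0.16 without mutant replicate 4 and 0.078 in thinned cells. Of its members only xirp1, an actin-binding repeat protein gene, was called over all genes (0.87, SE 0.22, edgeR adjusted p = 0.0448; DESeq2 called none), and 4 rose when adjusted over the list alone. BAG3 and HSPB8, which act together in protein quality control, stood at 0.92 and 0.91. The reporter's own gene nppa was at 350.5 ± 87.9 and 503 ± 100.8 CPM (SD, n = 3 and 4; log2 fold change 0.51, SE 0.19, edgeR adjusted p = 0.18) and nppb at 148.7 ± 18.5 and 236.06 ± 96.8 CPM (edgeR adjusted p = 0.39). The gate was set on nppa reporter signal. Per cell, 0.233% ± 0.0577 of thinned transcripts came from the list in wild-type plates (SD, n = 3) and 0.375% ± 0.0957 in mutant plates (SD, n = 4; exact permutation p = 0.171, two-sided), with differences of 0.15 in run 1 and 0.1 in run 2. Without thinning the shares were 0.246% and 0.373% (exact permutation p = 0.229, two-sided), and without nppa the thinned difference was 0.0417 (exact permutation p = 0.714, two-sided).

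Among mitochondrial and metabolic genes, 12 of 13 mitochondrially encoded genes had a positive fold change, and the list was higher in mutant plates (median 0.47, camera adjusted p = 0.000152; adjusted p = 0.701 with an estimated correlation). MT-ATP6 (0.54, SE 0.12) and MT-ND5 (0.70, SE 0.16) were called over all genes and 6 rose when adjusted over the list alone; MT-CO1 and MT-CO3 stood at 0.50 and 0.47. Limma with equal weight of cells called no member. The median mitochondrial share of kept cells was also higher in both mutant plates of run 1; without these plates the list median was 0.49. In thinned cells it was 0.26 and the list did not pass (camera adjusted p = 0.111). Nuclear-encoded respiratory chain genes were lower as a list (68 genes, 20 with a positive fold change, median -0.12, camera adjusted p = 0.0387; adjusted p = 0.791 with an estimated correlation). No member was called by edgeR over all genes or adjusted over the list alone, none by DESeq2 and 1 by limma, while 10 had an unadjusted edgeR p under 0.05. Without mutant replicate 4 the list moved to a smaller median and did not pass (camera adjusted p = 0.263). The genes ATP5F1D, NDUFB1, cycsb and SDHA stood at -0.42, -0.48, -0.38 and 0.80. Both called fatty acid genes fell, ACADVL of mitochondrial beta-oxidation by 0.72 and the fatty acid binding protein gene FABP3 by 0.56 on the log2 scale, also when adjusted over the list alone. PPARGC1A and ACADSB stood at -0.80 and 0.65, and the list did not pass (20 genes, camera adjusted p = 0.639). Glycolysis (8 genes, camera adjusted p = 0.734; PGAM2 -0.41, PDK4 -0.45, HK1 0.43, pgam1a 0.28) and the tricarboxylic acid cycle (20 genes, camera adjusted p = 0.777; SUCLG2 0.83, FH 0.37, ogdha 0.25) had no called member in edgeR, DESeq2 or limma, nor in edgeR adjusted over the list alone. Each had 2 members at an unadjusted edgeR p under 0.05. With extended matching, added after seeing the data, 22 glycolysis genes were tested and 14 had a positive fold change. None was called by edgeR over all genes, but 3 rose when adjusted over the list alone. The list again did not pass (camera adjusted p = 0.259).

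Cytosolic ribosomal protein genes were lower as a list (65 genes, 9 with a positive fold change, median -0.17, camera adjusted p = 8.84e-05; adjusted p = 0.791 with an estimated correlation). The median was -0.39 in run 1 alone and -0.10 in run 2 alone, where the list did not pass (camera adjusted p = 0.114). RPS21 was the member called over all genes (-0.60, SE 0.15), none passed when adjusted over the list alone, and RPS26 (ENSDARG00000030408), RPS28 and RPL22 stood at -0.47, -0.40 and -0.37. Immediate early and heat shock genes were higher as a list (14 genes, 12 with a positive fold change, median 0.27, camera adjusted p = 0.037; adjusted p = 0.701 with an estimated correlation). The median was 0.86 in run 1 alone, where the list did not pass (camera adjusted p = 0.124), and 0.69 without mutant replicate 3. ATF3 and JUND were called over all genes, 3 members rose when adjusted over the list alone, and hsp70.3 and hsp70l stood at 1.29 and -0.68. The hsp70l value was 0.37 in run 1 alone and -1.22 in run 2 alone, where it passed as lower (edgeR, adjusted p under 0.05). Of 6 tested genes of the high mobility group list none was called over all genes in edgeR, DESeq2 or limma, and 1 had an unadjusted edgeR p under 0.05 and rose when adjusted over the list alone (camera adjusted p = 0.487). Their log2 fold changes included hmgn6 0.58, the paralog hmga1b 0.88 and hmgb2b 0.35. No list call held with an estimated correlation or in fry (smallest adjusted p 0.223), and other splits of the plates called as many lists.

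**Figure D3:**
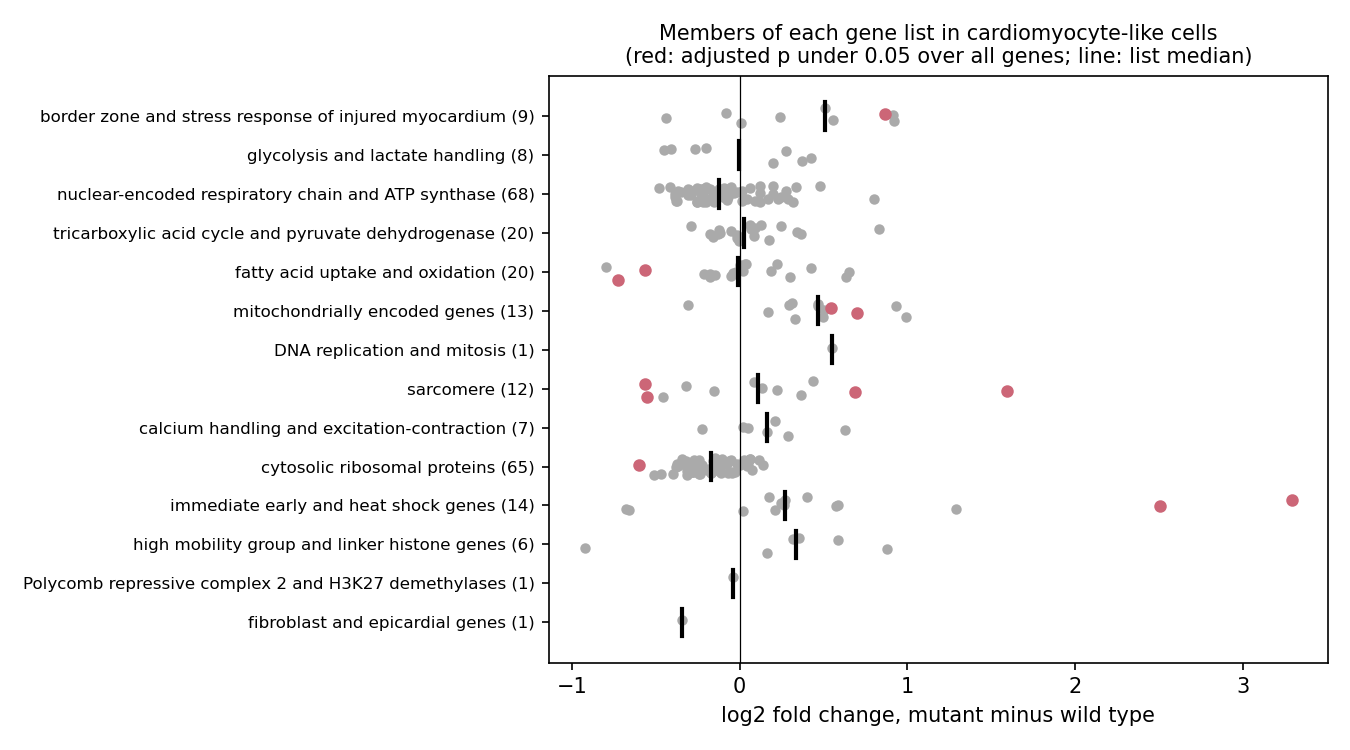
Log2 fold change (mutant minus wild type) of every tested member of each gene list in cardiomyocyte-like cells, with the number of members in brackets. Each point is a gene, red where its adjusted p over all genes was under 0.05, and the black line is the list median, 0.47 for mitochondrially encoded and -0.17 for cytosolic ribosomal protein genes.

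Replication and mitosis transcripts were rare. At least 2 of them were found in 2.65% ± 2.31 of thinned wild-type cells (SD, n = 3) and 5.18% ± 2.15 of thinned mutant cells (SD, n = 4; exact permutation p = 0.2, two-sided). Without thinning the shares were 6.75% and 9.14%. The difference was 6.88 percentage points in run 1 and -0.484 in run 2. PCNA was the list's 1 gene abundant enough to be tested (0.55, SE 0.48, edgeR adjusted p = 0.621). In the Polycomb and fibroblast lists kdm6bb (-0.04, camera adjusted p = 0.943) and podxl (-0.34, camera adjusted p = 0.639) were the tested members, the first with a test direction opposite to its fold change. The endothelial, leukocyte, erythrocyte and thrombocyte lists had none.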

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

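PPARGC1A stood apart in mutant replicate 2 at 69.9 CPM, against 39.4 to 43.2 CPM in the other mutant plates; 79 groups were looked at and chance flags about 1 in 20. The 91 unnamed cells, which are outside the comparison of cardiomyocyte-like cells, carried transcripts of other cell types above what 3 transcripts would give (0.068 per 10000). They held 28.2 macrophage and leukocyte transcripts per 10000, 5.31 fibroblast and epicardial, 1.68 endocardial and endothelial and 0.204 thrombocyte transcripts per 10000, against 0.286, 1.79, 0.027 and 0.014 in cardiomyocyte-like cells. They also held 1980.4 mitochondrially encoded and 417.8 ribosomal protein transcripts per 10000, against 268.2 and 988.03 in cardiomyocyte-like cells. Mutant replicate 1 alone held 893 of the 1244 macrophage and leukocyte transcripts (59.03 per 10000), and mutant replicates 2 and 3 held none. Wild-type replicate 3 held 17.3 fibroblast and epicardial transcripts per 10000, against at most 4.37 in any other plate.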

How the results depend on the processing

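The alternatives with thinned cells, other cluster resolutions or class rules for the gene tests, extended list matching and lists of at least 3 tested genes were chosen after seeing the data. So were those that left out both mutant plates of run 1, the cluster mostly of one plate or the most abundant gene without a symbol. The alternatives of the count over all kept cells were also chosen then. No paired analysis was possible because nothing in the labels pairs plates of the 2 genotypes.

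The 68 genes called in cardiomyocyte-like cells became 38 without the run covariate, 45 in run 2 alone, 36 with a cell minimum of 2000 and 14 over all kept cells, and 40 to 69 with 1 plate left out (40 without wild-type replicate 1, 44 without wild-type replicate 3). The 14 over all kept cells became 9 without the run covariate and 83 with no low-count filter, and 7 to 20 with 1 plate left out (7 without wild-type replicate 1, 9 without wild-type replicate 2 or 3). Of 33 named genes past the threshold, 6 passed in each alternative in which they were tested: KCNV1, hspb6, RBP2, FAM107B, ifitm1 and ATF3.

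The hmga1a change kept its sign in 26 alternatives and passed in 11. It was -1.67 with DESeq2 size factors and with the DESeq2 Wald test, and -1.70 with no low-count filter. In run 2 alone it was -2.24, and with a cell minimum of 500 it was -1.66. It was -1.65 with observed UMIs, with no smallest cluster size and without the most abundant gene that has no symbol. The others were -2.25 without both mutant plates of run 1, -1.89 without mutant replicate 1 and -2.23 without wild-type replicate 1. With 1 plate left out it lay between -2.23 and -1.12. It did not pass in run 1 alone (-0.74, edgeR adjusted p = 0.718) and was not tested in thinned cells. Run 1 alone holds 1 wild-type plate, which is assumed to vary like the mutant plates.

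The 4 lists called became 1 in run 1 alone, in run 2 alone and without both mutant plates of run 1, 2 with a cell minimum of 2000 and in thinned cells, 0 with an estimated correlation and 0 in fry, and 1 to 5 with 1 plate left out (1 without wild-type replicate 1, 2 without mutant replicate 4). The border zone list passed in 10 of 30 alternatives: no low-count filter (camera adjusted p = 0.00956), no run covariate (0.0115), a cell minimum of 500 (0.0428), equal weight of cells (0.0392), resolution 0.5 (0.00604), extended matching (0.00509), lists of at least 3 tested genes (0.0414, with 5 lists passing), and without wild-type replicate 2 (0.0322), mutant replicate 2 (0.0457) or mutant replicate 3 (0.00629). Its median was 0.16 without mutant replicate 4 and 0.078 in thinned cells. For lists that did not pass, the direction of the camera test turned, at these medians: with no low-count filter sarcomere 0.084, calcium handling -0.017 and Polycomb -0.21; without the run covariate tricarboxylic acid cycle -0.032; in run 1 alone glycolysis 0.11; in run 2 alone replication -0.038, sarcomere 0.066, calcium handling -0.041 and Polycomb -0.12; with a cell minimum of 500 Polycomb -0.16; at resolution 0.5 tricarboxylic acid cycle -0.021; without both mutant plates of run 1 tricarboxylic acid cycle -0.061, replication 0.12, sarcomere 0.06032, calcium handling -0.0495 and Polycomb -0.12; and with extended matching glycolysis 0.21 and replication -0.61. With 1 plate left out medians ranged from -0.056 to 0.099 for the tricarboxylic acid cycle, 0.079 to 0.15 for sarcomere, -0.00405 to 0.23 for calcium handling and -0.53 to 0.84 for Polycomb.

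Of named genes, over all kept cells ANXA2 changed by -0.14, MYH6 (ENSDARG00000079564) by -0.047, hsp70l by 0.61 and kdm6bb by 0.19. The log2 change of hsp70l was 0.37 in run 1 alone, but it passed as lower without wild-type replicate 1 (-1.225, edgeR adjusted p = 0.0147), in run 2 alone (-1.22) and without both mutant plates of run 1 (-1.23). That of PCNA was -0.038 in run 2 alone and -0.047 without both mutant plates of run 1, where that of trdn was -0.00248. That of hmgb2b was -0.065 in thinned cells. That of kdm6bb was 0.048 without sub-clusters, 0.02043 without the cluster mostly of one plate, 0.085 in the DESeq2 Wald test and 0.75 with equal weight of cells, where podxl was 0.015. With 1 plate left out PCNA ranged from -0.042 to 1.203, trdn from -0.094 to 0.58 and kdm6bb from -0.81 to 0.84. The difference in depth per kept cell was 28.4 transcripts with a cell minimum of 500 and -319.2 to 191.8 with 1 plate left out. Apart from the changes in which alternatives test fewer plates, cells or genes, the cause was not tested. Cell type shares, border zone scores and replication shares kept their direction with exact permutation p above 0.05 in each alternative. Within run 2, however, the difference in replication shares was -0.484 (-1.498 for at least 1 transcript, -1.23 without thinning), and that in border zone scores without nppa was 0. The difference in kept cells kept its sign in each alternative but was 9.5 in run 1. Depth limits the gene tests to 2171 of 16394 genes.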

Other observations

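The tests by other splits, by thinned cells, of the chromosomes of placed called genes and of handling during dissociation were chosen after the result was seen. Further genes past the threshold (edgeR, adjusted p under 0.05 over all genes) that the naming rule did not take were picked here after their values were seen. Both genes listed as titin, TTN (ENSDARG00000000563) and TTN (ENSDARG00000028213), were higher by 1.14 and 0.94 on the log2 scale, the filamin gene FLNC (ENSDARG00000018566) by 1.26, the actin gene ACTA1 (ENSDARG00000036371) by 0.97 and the myoglobin gene mb by 0.47. These are muscle genes picked among the 38 higher genes, while 30 were lower. Called muscle genes also fell, among them MYL7 (-0.56), cmlc1 (-0.55), ckmb (-2.48) and actc1c (-1.97). With extended matching the sarcomere list had 4 members called higher and 2 lower and did not pass as a list (20 genes, camera adjusted p = 0.322).

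1 of the 35 splits equals the sequencing runs and could not be fitted with the run covariate, which left 34. Of these, 1, the real one, called as many as 68 genes in cardiomyocyte-like cells, and the highest other count was 8. Many of the 34 splits change the numbers of plates per run, though the run is a batch. Only 18 of them keep these numbers, and among these the highest other count was again 8. That is too few for a share under 0.05, so chance assignment of plates within runs cannot be excluded at that bound. For all kept cells again 1 of 34 reached the real count of 14, with 4 as the highest other (2 within runs). For gene lists 7 of 34 splits called at least the real number of 4, with 6 as the highest other, so chance cannot be excluded for the number of lists called.

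Of the 68 called genes 48 were still tested when each cell was thinned to 1000 transcripts, and 30 of them were still called. Over these 48 genes 97.2% of the median absolute log2 fold change was left, so their change did not rest on deep cells weighing more. Thinning keeps the expected proportions within each cell. It therefore cannot tell whether composition that goes with depth gave these changes. The other 20 called genes were not tested this way. Variants inherited with the hmga1a locus are a candidate explanation for part of the called genes. By symbol, 45 of 68 called genes could be placed on a chromosome of the GRCz12tu assembly, 66.2%, which is too few for the test to count; of those, 4.44% shared the chromosome of hmga1a, as did 4.77% of uncalled genes (Fisher's exact p = 1.0, two-sided). Of the 45 placed genes 95.6% lay on another chromosome than hmga1a, which argues against linked variants in or near those genes themselves. For the other called genes, unplaced or on the chromosome of hmga1a, linked variants and an effect of the mutation cannot be told apart. Effects of a linked variant on genes elsewhere and a difference in strain background were not tested.

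Higher mitochondrially encoded and lower ribosomal protein transcripts had the same sign in each run alone, in 4 of 4 list medians (0.45 and 0.43 for the first list, -0.39 and -0.10 for the second), which argues against a difference between sequencing runs as the whole cause. With cells thinned to 1000 transcripts 157.2% of the ribosomal protein median was left (-0.27 against -0.17), so it did not rest on deep cells weighing more. Thinning keeps the expected proportions within a cell, so composition that goes with depth was not tested. For the mitochondrially encoded list 56.2% was left, between the bounds set beforehand. Depth per cell stays open for both lists. A difference in RNA quality, which may differ between plates, stays open for both.

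The immediate early and border zone genes did not fall back when clusters 7.1 and 7.2 were left out too. Without the whole parent cluster their median over 23 genes was 0.48 against 0.27, 176.8% of it. Clusters 7.3, 7.4 and 7.5 were unnamed and added to neither value, so only clusters 7.1 and 7.2 were tested here. Of 14 immediate early and heat shock genes 12 had a positive fold change in mutant plates, as handling during dissociation may also give. How plates were prepared is not given by genotype, so handling and genotype cannot be told apart for these genes.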
